A study of Mus musculus with 12 samples.

How the data were processed

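Sequencing, trimming and counting were done by the submitters. Read counts per gene were deposited as 1 table of 57010 Ensembl genes by 12 samples, and per the submitters' processing notes they came from Trim Galore, HISAT2 and featureCounts with the GRCm39 build, without versions or settings. Per the labels' protocols, RNA was isolated with TRIzol, treated with DNase I, required to reach a RIN of at least 8 and made into libraries with a TruSeq RNA kit. The strand setting, read length, annotation release and rule for reads with several matches are not given in the sources used here, so counts of near-identical copies, overlapping genes and antisense genes are uncertain. Groups were taken from the labels and were never set from the data. The titles call the saline knockout samples sham, while their treatment label is saline.

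Gene symbols were added by Ensembl identifier from GENCODE M21, which annotates GRCm38. It named 52029 genes holding 99.4% of the counts. Positions from it served only to tell which genes are neighbours. Of the 1041 distinct symbols in the 37 gene lists 1037 were in the table.

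The tests, alternatives, gene lists and naming rule were chosen before the data were examined. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 19166, of which 18746 had a symbol. Counts were scaled by TMM and fitted with edgeR's robust quasi-likelihood model on 3 group means, with 9 residual degrees of freedom and a common biological coefficient of variation of 0.152. Each comparison was a contrast of that fit, and genes with a Benjamini-Hochberg adjusted p under 0.05 are said to have changed, risen, fallen or been called. Fold changes are log2 with the fit's prior count of 0.125, and SE is the absolute log2 fold change over the square root of F. CPM values use library totals of the tested genes scaled by TMM, and a prior count of 2 was added where a library's level is given on the log2 scale. Group values are means ± SD over 4 libraries. A gene without counts in a group was given a floor of 3 counts over that group.

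Gene lists were tested with limma's camera at a preset correlation of 0.01 where at least 5 members were tested, adjusted by Benjamini-Hochberg over the lists within each comparison, and repeated with an estimated correlation and with fry. Members were also adjusted over their own list alone. The lists were IL-17 signalling and targets, interferon-stimulated genes, cytokines, chemokines and NF-kB targets, microglia markers, activated microglia, MHC class I antigen presentation, complement, and markers of Purkinje cells, granule cells, cerebellar interneurons, astrocytes and Bergmann glia. They also covered reactive astrocytes, oligodendrocytes and myelin, oligodendrocyte precursors, endothelial and mural cells, choroid plexus and ependyma, meninges and fibroblasts, lymphocytes, neutrophils and monocytes, erythrocytes, and brainstem and deep nuclei. The others were immediate early genes, glutamatergic synapse, GABAergic synapse, ion channels of Purkinje cell firing, FMRP-bound transcripts, autism risk, nuclear oxidative phosphorylation, mitochondrially encoded genes, cytosolic ribosomal proteins, heat shock and unfolded protein response, glucocorticoid-responsive genes, circadian clock, cholesterol biosynthesis, brain extracellular matrix, axon and cytoskeleton, and sex-linked expression.

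Named genes are Fmr1, Il17a, Il17ra and Il17rc, the 10 largest rises and 10 largest falls per comparison among called genes with a mean log2 CPM of at least 1 and no overlap between groups, and up to 4 members per list by smallest p. Predicted and unnamed genes were counted but not named, and some genes that the rule names are not reported here. A called gene outside this rule is said to have been chosen after its values were seen. Opposite changes were set beside simulated counts in which the groups share the saline knockout libraries. Library measures were compared with exact permutation tests and positions with two-sided Fisher's exact tests.

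Alternatives were DESeq2, limma-voom, RLE and upper quartile scaling, no filter, a filter of at least 10 counts in 8 libraries, a fit of only the 2 groups compared, a replicate block, a fit without robust estimation, 1 surrogate variable, an adjusted p under 0.1, a log2 fold change of at least 1, and leaving out each library. Leaving out the libraries with Ttr above 1000 CPM, adding log2 Ttr as a covariate, and counting pairs of called genes within 5 Mb were added after seeing the data. On simulated counts with 100 genes changed 2-fold among 19166, 68%, 60% and 74% were recovered for genotype, treatment and treated knockout against FVB, and with 100 changed 1.5-fold 48%, 56% and 51%. False calls were 6.67%, 4.48% and 2.92% of all calls, a list of 40 genes shifted 1.3-fold was called in each comparison, and 0 of 30 unshifted lists were. The simulated genes varied independently of one another. These list results therefore give no rate of false calls for lists whose members vary together. Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.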

Results

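Gene expression was measured by bulk RNA sequencing in mouse cerebellum, which the series title narrows to crus 1, a lobule of the lateral cerebellar hemisphere. The 12 libraries fell into 3 groups of 4: FVB mice given saline, Fmr1 knockout mice given saline, and Fmr1 knockout mice given poly(I:C) by injection into the peritoneal cavity. FVB is an inbred mouse strain. Fmr1 encodes FMRP, an RNA-binding protein whose loss causes fragile X syndrome in people, and poly(I:C) is a synthetic double-stranded RNA that mimics viral infection. FVB mice given poly(I:C) were not among the samples, so whether the response to poly(I:C) depends on genotype was not tested. The libraries held 35.2 to 48.7 M counts in FVB, 38.7 to 50.2 M in the saline knockout and 39.4 to 56.4 M in the treated knockout, and 25300 to 27565 genes were detected in each. A total of 3 counts over a group, taken as the floor for genes with none, corresponded to 0.0189, 0.0179 and 0.0159 counts-per-million (CPM) in these groups, and such floors cover counting error only. The labels name separate samples but not separate animals, so p-values measure the spread between these samples.

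Fmr1 was measured first, as a check of the genotype labels. Its level was 91.8, 85.5, 95.0 and 108 CPM in FVB 1 to 4, 28.7, 33.6, 27.9 and 36.8 CPM in saline knockout 1 to 4, and 33.9, 34.6, 36.0 and 33.9 CPM in treated knockout 1 to 4. The saline knockout kept 33.4% of the FVB level and the treated knockout 36.4%, and every knockout library lay below every FVB library. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 fold change against FVB was −1.58 (SE 0.0884, adjusted p = 8.74e-09) in the saline knockout and −1.46 (SE 0.0879, adjusted p = 1.59e-09) in the treated knockout. Between the knockout groups Fmr1 differed by 0.12 on the log2 scale (edgeR, adjusted p = 0.557). Counts were summed over the whole gene, and the position of the targeted change within it is not given in the sources used here.

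The series title names IL-17A, a cytokine of T cells and other lymphocytes. Il17a had 0 counts in all 12 libraries, so its transcript was not detectable at this depth. Il17f had 4, 4 and 1 counts over the FVB, saline knockout and treated knockout groups, Il17b had 2, 4 and 0, and Il17c had 5, 1 and 8. Il17d, which brain tissue expresses, was at 7.28 ± 1.60, 6.07 ± 2.01 and 6.95 ± 1.12 CPM (SD, n = 4). The receptor chain Il17ra was at 12.98 ± 1.59 CPM in FVB, 12.3 ± 1.64 in the saline knockout and 16.2 ± 1.52 in the treated knockout (SD, n = 4). Its difference between treated and saline knockout was 0.40 (SE 0.114) on the log2 scale and missed the threshold by edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.0656), although all 4 treated libraries lay above all 4 saline ones. That difference passed by DESeq2 (adjusted p = 0.0187), without the low-count filter (0.0335) and without saline knockout 1 (0.0263). Saline knockout 1 had the highest Il17ra of its group (14.8 CPM against 11.4 to 11.6 CPM), and leaving out any other library gave no pass. Nor did the difference pass by limma-voom, with RLE or upper quartile scaling, with 1 surrogate variable or with log2 Ttr as a covariate. Against FVB, Il17ra in the treated knockout differed by 0.33 (edgeR, adjusted p = 0.0963, and 0.0487 without FVB 1). Il17rc, the partner chain, was at 3.58 ± 0.557, 3.69 ± 0.576 and 4.17 ± 0.684 CPM and passed in none of the 3 comparisons (edgeR, adjusted p = 0.963, 0.695 and 0.515).

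Markers of the choroid plexus, the tissue inside the ventricles that secretes cerebrospinal fluid, set 3 libraries apart. Ttr, the transthyretin gene, reached 4156 CPM in saline knockout 2, 2167 in treated knockout 2 and 2631 in treated knockout 3, against 1.63 to 65.3 CPM in the other 9 libraries. These are 1 saline knockout and 2 treated knockout libraries and no FVB library, so many of the counts below are also given without them, an alternative chosen after seeing the data that left 4, 3 and 2 libraries in the groups. Of all 41 library measures compared between groups (list means, total counts, genes detected and the shares of mitochondrial counts and of the 10 most abundant genes), none passed an exact permutation test after Benjamini-Hochberg adjustment (lowest adjusted p = 0.234 for genotype, 0.130 for treatment and 0.107 for treated knockout against FVB). Such an exact test of 4 against 4 libraries cannot give a p below 0.0286. Over 41 measures, a measure at that floor passes adjustment only if most of the others reach it too. Even the interferon list mean, 4.66 in the treated and 1.82 in the saline knockout, did not pass (exact permutation test, adjusted p = 0.130). The test therefore cannot show that the libraries were alike. The first principal component held 29.2% of the variance, with scores of −40.0 to −28.0 in FVB, −10.6 to 3.69 in the saline knockout and 29.4 to 52.3 in the treated knockout. Within the knockout groups the libraries high in Ttr scored highest. Saline knockout 2 was at 3.69, and treated knockout 2 and 3 at 44.8 and 52.3 against 29.4 and 31.6 for treated knockout 1 and 4. Ddx3y, a gene of the Y chromosome, was at 70.4, 64.8 and 67.6 CPM in the 3 groups and Xist, which females express, had at most 23 counts in any library.

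**Figure D1:**
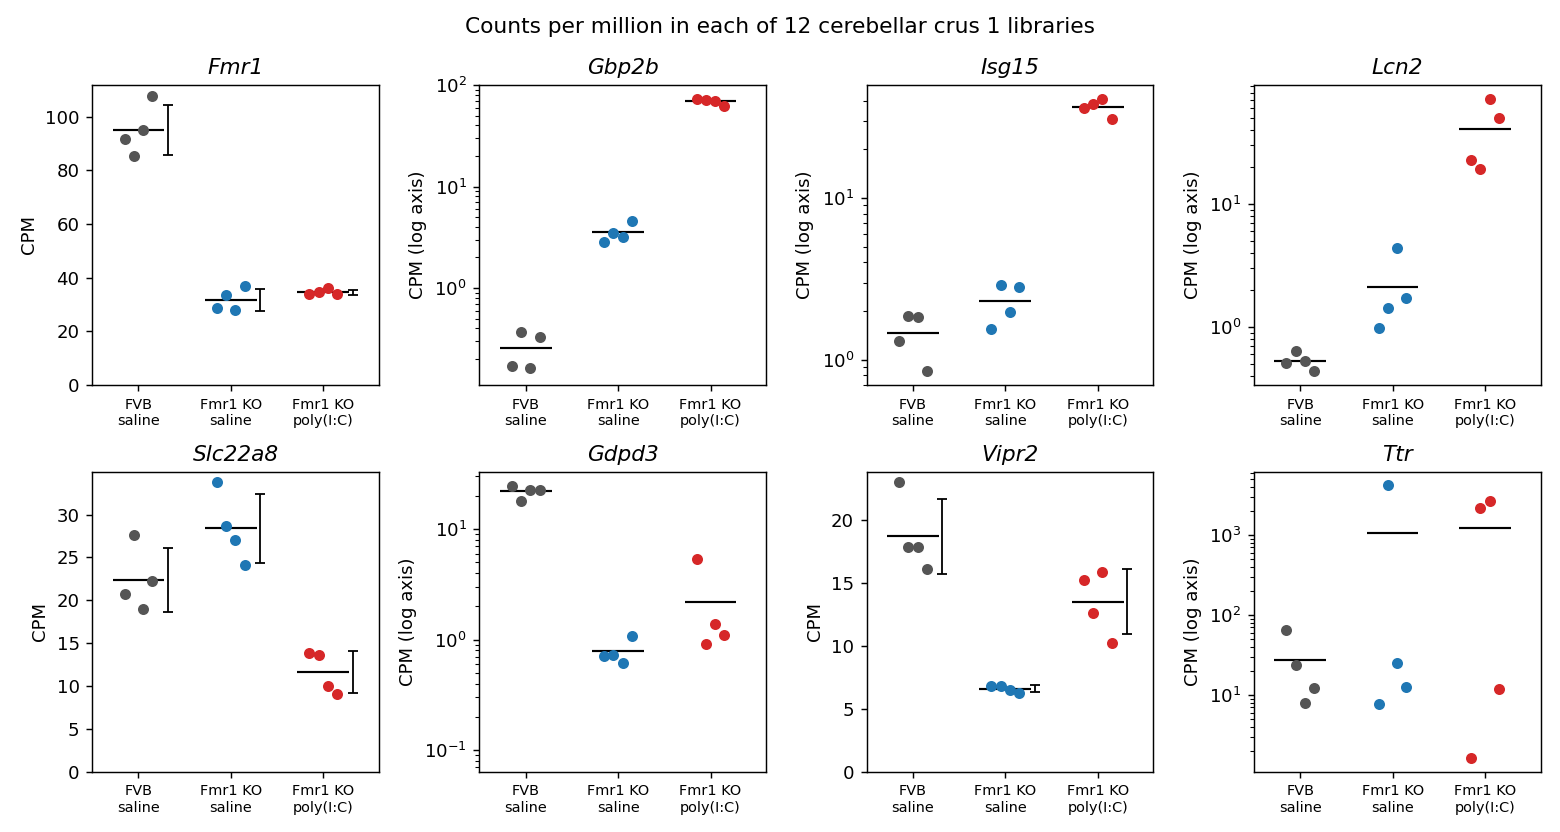
CPM of 8 genes in each library, by group (FVB saline, Fmr1 knockout saline, Fmr1 knockout poly(I:C)); points are libraries, bars are group means, and error lines are SD on the linear axes of Fmr1, Slc22a8 and Vipr2, while the other genes are on log axes. Fmr1 lies near 95.0 CPM in FVB and near 31.7 and 34.6 CPM in the knockout groups, and Ttr is highest in saline knockout 2 and treated knockout 2 and 3.

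Saline knockout against FVB, called genotype here, compares the knockout line with FVB mice without an immune stimulus and does not separate loss of Fmr1 from other differences between the lines. Gdpd3, which encodes an enzyme of lysophospholipid breakdown, was at 0.783 ± 0.205 CPM in the saline knockout and 21.99 ± 2.89 CPM in FVB (SD, n = 4), a log2 fold change of −4.79 (SE 0.576). Slc15a2, a peptide transporter, fell from 63.0 to 20.3 CPM (log2 −1.64, SE 0.166), Vipr2, a receptor for vasoactive intestinal peptide, from 18.7 to 6.59 CPM (−1.50, SE 0.138), and Itpr3, an inositol trisphosphate receptor, from 21.0 to 9.50 CPM (−1.15, SE 0.118). Gbp2b, an interferon-inducible GTPase, rose from 0.258 to 3.54 CPM (3.801, SE 0.214), Nxpe4 from 4.26 to 14.1 CPM (1.73, SE 0.141), and Ogfrl1 from 73.2 to 222 CPM (1.60, SE 0.132). In total 294 of 19166 tested genes changed by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, 156 up and 138 down, and 128 of them by at least 2-fold (80 up, 48 down). Of all tested genes, 7.02% had no overlap between the 4 and 4 libraries, where chance gives 2.86%.

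The other genes among the 10 largest rises were Rpl34 (3.18), Lipo3 (2.06), Itgal (1.84), Lyrm7 (1.69), Nuf2 (1.60), Fxyd7 (1.55) and Alpk1 (1.55). The other largest falls besides Fmr1 were Col6a3 (−1.35), Zfp605 (−1.26), Fcrls (−1.20), Itpripl2 (−1.15) and Crlf2 (−1.11). All are log2 fold changes, with adjusted p by edgeR from 6.44e-05 to 0.0374. Rpl34, a ribosomal protein gene, and Gbp2b have near-identical copies elsewhere in the genome, and their counts are uncertain because the rule for reads with several matches is not given in the sources used here. Npsr1, a neuropeptide S receptor gene chosen after its values were seen, was at 6.06 ± 0.676 CPM in FVB and had no counts in the saline knockout, at least 339-fold lower. Ifi44l, an interferon-induced gene also chosen after its values were seen, had no counts in FVB and 0.477 ± 0.161 CPM in the saline knockout, at least 25.2-fold higher. Leaving out FVB 1, 2, 3 or 4 lowered the number of called genes to 176, 194, 156 and 161, leaving out saline knockout 2 lowered it to 182, DESeq2 called 627, and edgeR without the low-count filter called 506. With log2 Ttr as a covariate 287 genes were called, 247 of them among the 294. Without the 3 libraries high in Ttr 229 genes were called (135 up, 94 down), 185 of them among the 294. Of the 20 genes named for size all but Itgal passed there (edgeR, 0.191). Leaving out single libraries ended the calls of Itgal (FVB 1, 3 and 4, each saline knockout library and treated knockout 2 and 3, adjusted p = 0.0549 to 0.123), Alpk1 (each FVB library and saline knockout 1 to 3, 0.0613 to 0.0889, and 0.121 by limma-voom) and Lyrm7 (FVB 4, 0.0525).

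Genes of neutrophils and monocytes were higher in the saline knockout. S100a8, a calcium-binding alarmin of neutrophils, rose from 0.146 to 2.62 CPM (log2 4.14, SE 0.712), and Ltf, the lactoferrin gene, from 0.126 to 2.36 CPM (4.15, SE 0.884). S100a9 rose from 0.586 to 5.29 CPM (3.17, SE 0.643). Of the list's 17 tested members 4 passed and 13 did not, 9 rose adjusted over the list alone, and the median log2 fold change was 2.10. DESeq2 called 9 of the 17 and limma-voom 0 (adjusted p = 0.0545 for S100a8, 0.0513 for S100a9 and 0.0808 for Ltf). The list was called by camera with a preset correlation (adjusted p = 1.99e-10), a call lost at adjusted p = 0.508 with an estimated correlation. By edgeR, each FVB library ended the calls of S100a8 (adjusted p = 0.0544 to 0.0637), S100a9 (0.0645 to 0.136) and Ltf (0.124 to 0.142) when left out. Leaving out saline knockout 2 ended those of S100a9 (0.0942) and Ltf (0.0940), and saline knockout 4 those of S100a9 (0.0509) and Ltf (0.0654). Treated knockout 1, 2 and 4 did so for that of S100a9 (0.0546, 0.0645 and 0.0620) and treated knockout 2 and 4 that of Ltf (0.0666 and 0.0682). Of 18 members tested without the 3 libraries high in Ttr 2 were called, and the median was 2.17.

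Cholesterol biosynthesis genes were higher as a group. All 25 members had a positive fold change. Of these 2 rose, among them Sc5d, the lathosterol desaturase (74.1 to 110 CPM, log2 0.58, SE 0.0779). The other 23 did not pass and 8 rose adjusted over the list alone. The list's adjusted p by camera was 1.27e-10, and adjusted p = 0.595 with an estimated correlation. Of the 25 members 24 stayed positive without the 3 libraries high in Ttr, and 2 were called. The rise as a group was not seen in treated knockout against FVB. There 13 of 25 were positive, 2 of them called by edgeR, with a median of 0.02 (camera adjusted p = 0.529). Of the 46 interferon-stimulated genes 39 had a positive fold change, with a median of 0.28. However, edgeR's quasi-likelihood test called 0 of them (11 at an unadjusted p under 0.05, DESeq2 1, limma-voom 0), and 0 adjusted over the list alone. That list was called by camera at adjusted p = 4.38e-06 and lost at adjusted p = 0.642 with an estimated correlation, and without the 3 libraries 36 were positive with a median of 0.15.

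Of the neuronal gene lists 5 were called lower at the preset correlation, by small amounts, while granule cell markers (median 0.0033, camera adjusted p = 0.839), Purkinje cell markers (0.132), autism risk genes (0.147) and axon and cytoskeleton genes (0.812) were not called. Among markers of cerebellar interneurons 1 of 20 fell by edgeR (Sorcs3, a sorting receptor, −0.41, SE 0.0973), 5 adjusted over the list alone, and camera gave adjusted p = 6.40e-04. Among ion channels of Purkinje cell firing 1 of 34 fell (Kcnd3, a potassium channel, −0.26), 4 adjusted over the list alone (camera 2.26e-04). Among GABAergic synapse genes 1 of 26 fell (Gabra3, a GABA receptor subunit, −0.48), 2 adjusted over the list alone (camera 1.92e-03). Of 46 glutamatergic synapse genes edgeR's quasi-likelihood test called 0 (12 at an unadjusted p under 0.05, DESeq2 4, limma-voom 0), with 1 up and 4 down adjusted over the list alone (camera 9.24e-04). Of 51 tested FMRP-bound transcripts 1 fell (Adcy5, an adenylyl cyclase, −0.36, SE 0.0700), 2 adjusted over the list alone (camera 1.20e-03). With an estimated correlation these 5 calls were lost, at adjusted p = 0.642, 0.595, 0.642, 0.642 and 0.846 in that order, and the FMRP-bound list was also lost without saline knockout 4 (0.142). Limma-voom did not call Sorcs3 (adjusted p = 0.0586) or Gabra3 (0.0558). The edgeR calls of Sorcs3, Kcnd3 and Gabra3 ended without the 3 libraries high in Ttr (adjusted p = 0.137, 0.0575 and 0.0685) and without FVB 1 (0.128, 0.0942 and 0.108), and other single libraries ended them too (0.0519 to 0.132, 0.0533 to 0.0884 and 0.0640 to 0.114).

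The remaining called lists rested on 1 or no member. Microglia markers were lower, with 1 of 27 called, Fcrls, also adjusted over the list alone (camera 0.0303, and adjusted p = 0.846 with an estimated correlation). That call ended without FVB 2 (0.209), saline knockout 1 (0.160) or 2 (0.226) and without the 3 libraries high in Ttr (0.234). Cytosolic ribosomal protein genes were higher, with 1 of 78 called, Rpl34, also adjusted over the list alone (camera 0.00339, and adjusted p = 0.846 with an estimated correlation), and the call ended without FVB 1 (0.0594), saline knockout 3 (0.0622) or 4 (0.241). Of 20 genes of MHC class I antigen presentation edgeR's quasi-likelihood test called 0 (4 at an unadjusted p under 0.05, DESeq2 2, limma-voom 0) and 2 were higher adjusted over the list alone (camera 0.0303, adjusted p = 0.846 with an estimated correlation). This call ended without FVB 1 (0.0797), 3 (0.123) or 4 (0.103). Of 24 choroid plexus and ependymal markers it called 0 (1 at an unadjusted p under 0.05, DESeq2 1, limma-voom 0) and 0 adjusted over the list alone, with a median of 1.70 (camera 0.00195, adjusted p = 0.846 with an estimated correlation). The median was −0.03 without the 3 libraries high in Ttr (camera adjusted p = 0.781, and 0.709 without saline knockout 2 alone). Outside the called lists, Il18, an inflammasome cytokine, fell (−1.02, SE 0.149), as did Plcb3, a phospholipase of Purkinje cells (−0.39, SE 0.0679), and Nptx2, a neuronal pentraxin (1.62 to 0.404 CPM, −1.97, SE 0.357). Hspa8, a constitutive heat shock protein gene, rose from 1161 to 1852 CPM (0.67, SE 0.0959) and Itih3, an astrocyte gene, from 126 to 180 CPM (0.52, SE 0.0872). Hspa8 lies in the same block of chromosome 9 as Sc5d.

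Treated against saline knockout shows the response to poly(I:C). Interferon-stimulated genes rose together: Irf7, the transcription factor that amplifies interferon signalling, went from 3.57 to 81.6 CPM (log2 4.51, SE 0.303), and Ifi44 from 1.79 to 50.4 CPM (4.79, SE 0.287). Rsad2, the antiviral enzyme viperin, went from 1.198 to 25.3 CPM (4.41, SE 0.203), and Isg15, a ubiquitin-like protein, from 2.31 to 36.5 CPM (3.98, SE 0.223), each without overlap between the 4 and 4 libraries. Lcn2, which encodes the iron-binding protein lipocalin 2, rose from 2.13 to 40.8 CPM (4.26, SE 0.573). Slc22a8, an organic anion transporter of the brain barriers, fell from 28.4 to 11.6 CPM (−1.28, SE 0.152), Slc40a1, the iron exporter ferroportin, from 10.9 to 4.33 CPM (−1.33, SE 0.173), and Opalin, a myelin membrane protein gene, from 14.1 to 5.80 CPM (−1.27, SE 0.175). In total 550 of 19166 genes changed by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, 347 up and 203 down, and of the 250 that changed at least 2-fold 220 were up and 30 down. Of all tested genes, 9.75% had no overlap between the groups, against 2.86% by chance.

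The other largest rises were Gbp2b (4.28), Ifit1 (3.88), Iigp1 (3.69), Oasl2 (3.59) and Oas1a (3.52). The other largest falls were Tmprss3 (−1.52), Tnc (−1.42), Megf6 (−1.35), Col2a1 (−1.32), Fbxl7 (−1.15), Vwf (−1.10) and Edn3 (−1.07), with adjusted p from 3.30e-12 to 0.0356. Without the 3 libraries high in Ttr 215 genes were called (179 up, 36 down, so that the share of rises was 83.3% in place of 63.1%), and 199 of the 550 were among them. That fit had 3 saline and 2 treated knockout libraries, so fewer calls can also come from fewer libraries. With every library kept and log2 Ttr as a covariate 519 genes were called, 62.8% of them rises, and 497 were among the 550. DESeq2 called 971, and leaving out treated knockout 3 gave 347. The edgeR calls of Tmprss3, Tnc, Col2a1, Vwf and Edn3 ended without the 3 libraries (adjusted p = 0.252, 0.330, 0.119, 0.0849 and 0.0916). That of Tnc also ended without any 1 of saline knockout 1 to 3 or treated knockout 2 to 4 (0.0511 to 0.0879), and that of Col2a1 without any 1 of FVB 3, saline knockout 3 and 4 or treated knockout 3 and 4 (0.0569 to 0.114). The call of Vwf ended without treated knockout 2 (0.0549) and that of Fbxl7 without saline knockout 1 (0.0580).

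Of the 46 interferon-stimulated genes 43 rose and 3 did not pass, 45 rose adjusted over the list alone, all 46 fold changes were positive, and the median log2 fold change was 3.00. The list kept its call with an estimated correlation (adjusted p = 7.37e-06), and 41 members were called without the 3 libraries high in Ttr. Of 20 genes of MHC class I antigen presentation 12 rose and 8 did not pass, 15 adjusted over the list alone. Among them were Nlrc5, the transactivator of class I genes (3.96, SE 0.219), the peptide transporter Tap1 (1.99, SE 0.182) and H2-Q4 (1.95), whose count is uncertain beside similar class I genes (camera 7.89e-31, adjusted p = 0.0129 with an estimated correlation). Of 28 reactive astrocyte genes 11 rose and 17 did not pass, with 14 up and 2 down adjusted over the list alone. They included Gbp2 (3.48, SE 0.220), the oncostatin M receptor Osmr (1.24, SE 0.158) and the ceruloplasmin gene Cp (1.05, SE 0.128) (camera 7.76e-20, adjusted p = 0.0128 with an estimated correlation). Of the 28 tested reactive astrocyte genes 12 were also on another list, among them Gbp2 on the interferon list. The reactive astrocyte call is thus not separate from the calls of those lists. Of 21 class I genes 8, and of 28 reactive astrocyte genes 7, were called without the 3 libraries. Both these lists and the interferon list kept their calls whichever single library was left out.

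Cytokines, chemokines and NF-kB targets rose in 13 of 32 cases and 19 did not pass, with 15 up and 1 down adjusted over the list alone. The chemokine genes Cxcl11 (0.428 to 20.6 CPM, log2 5.58, SE 0.410), Ccl2 (0.0965 to 1.94 CPM, 4.30, SE 0.632) and Ccl12 (0.401 to 2.57 CPM, 2.67, SE 0.385) rose, as did Ptgs2, the inducible cyclooxygenase (1.52 to 5.98 CPM, 1.97, SE 0.256). Camera gave adjusted p = 1.76e-12, and adjusted p = 0.0735 with an estimated correlation, and 6 members were called without the 3 libraries high in Ttr. By edgeR, of 22 IL-17 signalling genes and targets Lcn2 and Cebpd (1.28, SE 0.242) rose and the receptor Il17rd fell (−0.70, SE 0.182). The other 19 did not pass, with 3 up and 2 down adjusted over the list alone, and the list was not called (camera adjusted p = 0.381). Cebpd was not called by edgeR without the 3 libraries (0.126), nor Il17rd (0.208, and 0.0609 by limma-voom). The edgeR call of Il17rd also ended without any 1 of FVB 3 and 4 and the 8 knockout libraries except saline knockout 4 (adjusted p = 0.0555 to 0.140).

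Some endothelial and mural markers rose and others fell, and a few meningeal markers fell. Of 27 endothelial and mural markers 3 rose, among them the surface antigens Ly6a (12.4 to 82.0 CPM, 2.73, SE 0.172) and Ly6c1 (44.5 to 98.3 CPM, 1.15, SE 0.127). In the same list 6 fell, among them the angiopoietin receptor Tek (19.8 to 10.1 CPM, −0.97, SE 0.124) and Itm2a (82.1 to 39.7 CPM, −1.04, SE 0.145). The other 18 did not pass, with 4 up and 11 down adjusted over the list alone. Camera put the list down (adjusted p = 0.00693, and adjusted p = 0.632 with an estimated correlation), a call that ended without saline knockout 1 (0.0921) or treated knockout 4 (0.158). Of 26 meningeal and fibroblast markers 4 fell and 22 did not pass, with 2 up and 4 down adjusted over the list alone. Slc22a8, Slc22a6 (−0.68, SE 0.150) and Slc47a1 (−0.92, SE 0.213), which fell, transport organic ions (camera 0.0361, adjusted p = 0.855 with an estimated correlation). The meningeal call ended without saline knockout 1 (0.179) or 2 (0.0833) or treated knockout 4 (0.407). The edgeR calls of Slc22a6 and Slc47a1 ended without treated knockout 3 (0.0666 and 0.0574) or 4 (0.0607 and 0.0675), or in turn without saline knockout 1 (0.0601) and 4 (0.0580). Slc22a6 and Slc47a1 were at 0.151 and 0.0793 without the 3 libraries high in Ttr, where 3 endothelial markers were called up and 4 down, and 1 meningeal marker down.

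Of 25 cholesterol biosynthesis genes none had a positive fold change, with a median of −0.18. EdgeR's quasi-likelihood test called 0 (11 at an unadjusted p under 0.05, DESeq2 3, limma-voom 0), while 6 fell adjusted over the list alone. Camera called the list at adjusted p = 1.47e-05, lost at adjusted p = 0.632 with an estimated correlation, and 5 of the 25 fold changes were positive without the 3 libraries high in Ttr, with a median of −0.10. The list mean log2 CPM was 4.99 in FVB, 5.32 in the saline knockout and 5.11 in the treated knockout. The rise for genotype and this fall share the saline knockout libraries, so they are not separate results. Complement genes rose in 3 of 19 cases and 16 did not pass, 5 adjusted over the list alone. Among them were C1ra (1.84, SE 0.366) and C1qb (0.72, SE 0.156) (camera 5.05e-04, adjusted p = 0.632 with an estimated correlation). No member was called by edgeR without the 3 libraries high in Ttr (0.0626 for C1ra, 0.326 for C1qb). The call of C1qb also ended without saline knockout 1, 2 or 3 (0.0588, 0.0502 and 0.0503). Of 23 glucocorticoid-responsive genes 4 rose and 19 did not pass, 8 adjusted over the list alone, with Lcn2 first (camera 1.36e-04, adjusted p = 0.811 with an estimated correlation), and 1 was called without the 3 libraries. Of 28 heat shock and unfolded protein genes 3 rose and 25 did not pass, 5 adjusted over the list alone. They were Hspb1 (1.48, SE 0.267) and the near-identical Hspa1a (1.73, SE 0.233) and Hspa1b (1.82, SE 0.409), whose separate counts are uncertain. Camera gave adjusted p = 0.00395, and adjusted p = 0.632 with an estimated correlation. The list was at 0.110 without the 3 libraries, where edgeR called 1 member and Hspb1 was at 0.169 and Hspa1b at 0.518. The call of Hspa1b also ended without any 1 library except saline knockout 4 and treated knockout 1 (0.0696 to 0.131).

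**Figure D2:**
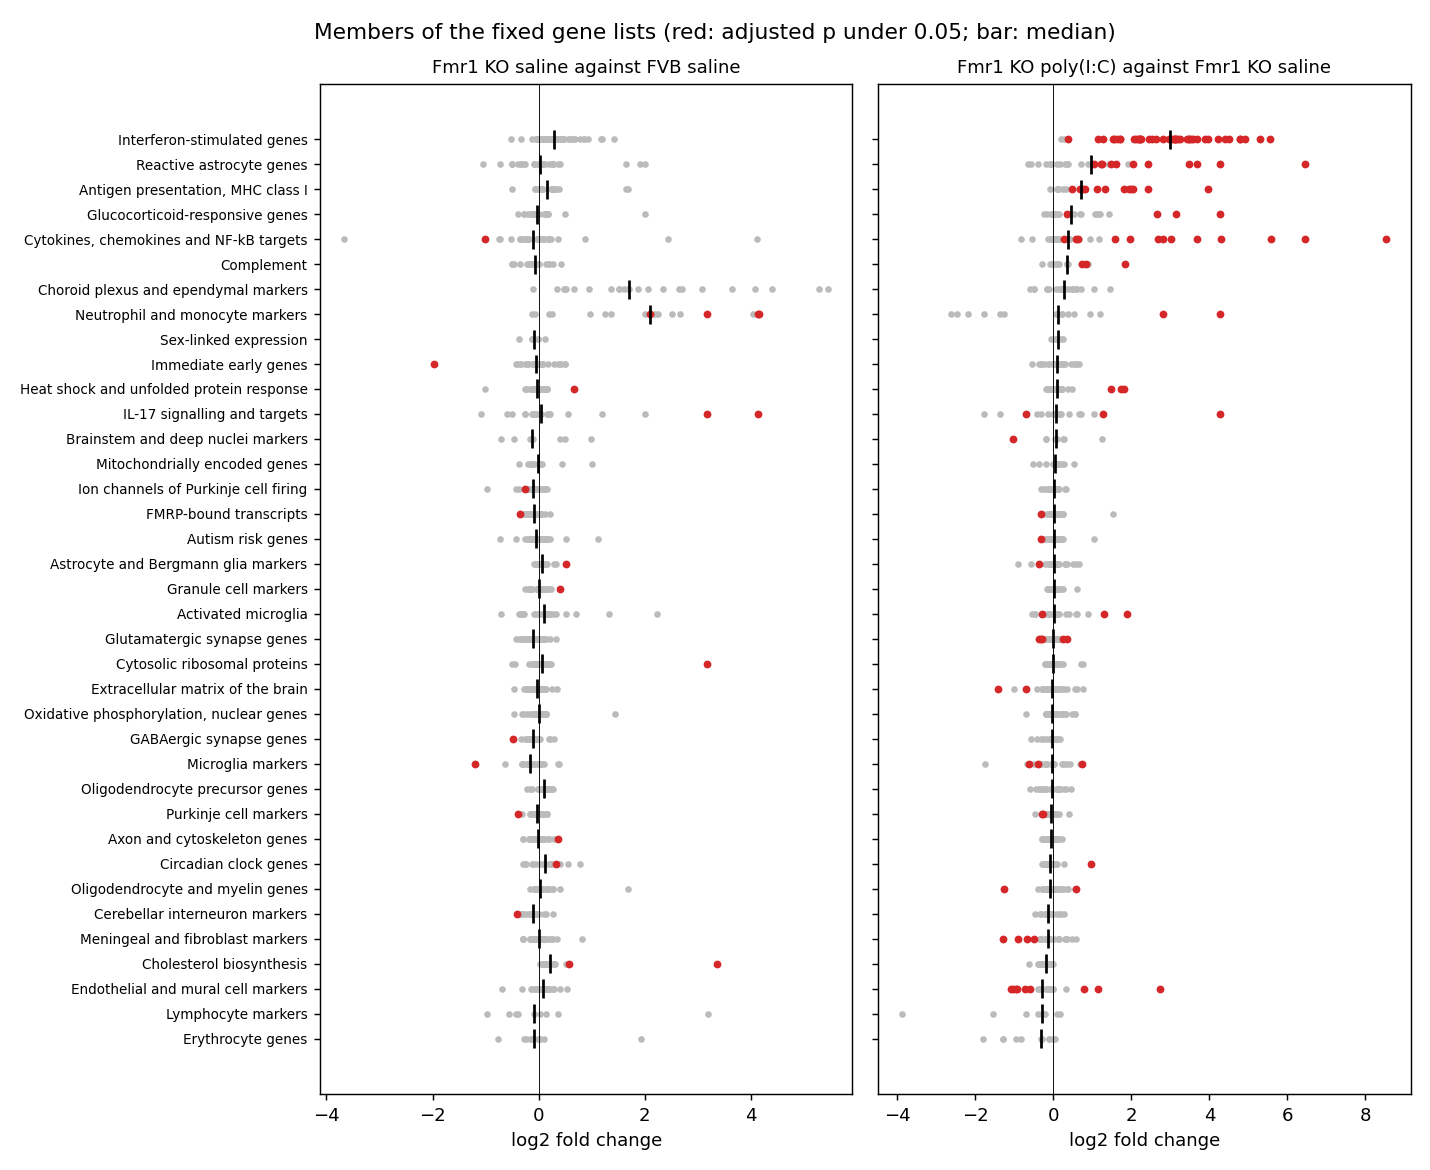
Log2 fold change of each tested member of the gene lists for saline knockout against FVB and for treated against saline knockout; red points passed at an adjusted p under 0.05 and vertical bars are list medians. For poly(I:C) 43 of 46 interferon-stimulated genes passed with a median of 3.00, and for genotype 0 of 46 passed with a median of 0.28.

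Treated knockout against FVB combines genotype and treatment. Gbp2b, which was higher in both separate comparisons, went from 0.258 CPM in FVB to 69.0 CPM (log2 8.08, SE 0.195), Lcn2 from 0.528 to 40.8 CPM (6.26, SE 0.674) and Ifi44 from 0.771 to 50.4 CPM (5.99, SE 0.316). Irf7 (5.10), Rsad2 (4.96), Isg15 (4.63), Ifit1 (4.34), Usp18 (4.33), Tgtp2 (4.23) and Oasl2 (4.01) followed, of which Tgtp2 has a near-identical copy, so its count is uncertain. Genes lower than in FVB included Gdpd3 (−3.30, SE 0.515), Hmcn1 (−2.94), Tmprss3 (−2.23), Catspere2 (−2.23), Slc15a2 (−1.88, SE 0.167), Col6a3 (−1.71), Adgre1, which encodes the macrophage antigen F4/80 (3.77 to 1.15 CPM, −1.71, SE 0.223), Tnc (−1.49) and Megf6 (−1.43), besides Fmr1. In total 1352 of 19166 genes changed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 731 up and 621 down, 439 of them at least 2-fold (345 up, 94 down), and 14.2% of tested genes had no overlap, against 2.86% by chance. With log2 Ttr as a covariate 990 genes were called, 948 of them among the 1352. Without the 3 libraries high in Ttr 556 genes were called (368 up, 188 down), 482 of them among the 1352. There 17 of the 20 genes named for size passed by edgeR, all but Gdpd3 (0.0588), Hmcn1 (0.248) and Tnc (0.107). Leaving out FVB 2 gave 900 treated knockout 3 gave 791 and 1 surrogate variable gave 805. The edgeR call of Hmcn1 ended without any 1 FVB library (0.0533 to 0.0624) or treated knockout 2, 3 or 4 (0.0714 to 0.0922). Npsr1 was again without counts in the treated knockout, at least 381-fold lower, and Ifi44l was at 10.6 ± 1.74 CPM, at least 563-fold higher.

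Of 46 interferon-stimulated genes 44 rose and 2 did not pass, also 44 adjusted over the list alone (median 3.16, adjusted p = 3.05e-05 with an estimated correlation), and 44 were called without the 3 libraries high in Ttr. MHC class I genes rose in 15 of 20 cases, also 15 adjusted over the list alone (adjusted p = 0.0136 with an estimated correlation). Reactive astrocyte genes, some of which are also on the interferon and class I lists, rose in 12 of 28 cases with 1 fall. Adjusted over the list alone 14 were up and 2 down (camera, adjusted p = 0.0136 with an estimated correlation). Cytokine genes rose in 14 of 32 cases with 2 falls, 15 up and 2 down adjusted over the list alone (camera 5.96e-08, adjusted p = 0.166 with an estimated correlation). In these 3 lists 9, 10 and 8 members were called up without the 3 libraries. Of 17 neutrophil and monocyte genes 4 rose, among them Plac8 (5.33, SE 0.571), Ly6c2 (3.20) and Lcn2, and 13 did not pass, 5 adjusted over the list alone (camera 4.01e-07, adjusted p = 0.254 with an estimated correlation), and 4 were called without the 3 libraries. Of 9 lymphocyte markers 3 fell and 6 did not pass, also 3 adjusted over the list alone, among them Ighm, the immunoglobulin mu chain gene (−0.94, SE 0.184) (camera 0.0137, adjusted p = 0.219 with an estimated correlation), and 1 was called without the 3 libraries.

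Interneuron markers were lower than in FVB: 6 of 20 fell and 14 did not pass, 10 adjusted over the list alone. Among them were Nos1, the neuronal nitric oxide synthase (250 to 160 CPM, −0.64, SE 0.102), Kit (307 to 212 CPM, −0.54, SE 0.110), Sorcs3 (−0.54, SE 0.0974) and Gad1, which makes GABA (755 to 596 CPM, −0.34, SE 0.0737). Camera called the list at adjusted p = 2.96e-05, lost at adjusted p = 0.405 with an estimated correlation. Of 30 Purkinje cell markers 4 fell and 26 did not pass, also 4 adjusted over the list alone, among them Plcb3 (−0.31, SE 0.0677) (camera 0.00263, adjusted p = 0.722 with an estimated correlation). GABAergic synapse genes fell in 4 of 26 cases, 8 adjusted over the list alone (camera 0.00161). Glutamatergic synapse genes fell in 4 of 46, 1 up and 6 down adjusted over the list alone (camera 0.00990). Ion channels of Purkinje cell firing fell in 6 of 34 with 1 rise, 2 up and 8 down adjusted over the list alone (camera 0.0128). These 3 calls were lost at adjusted p = 0.495, 0.609 and 0.609 with an estimated correlation. Without the 3 libraries high in Ttr only 1 interneuron marker, Nos1, was called among these 5 lists, by edgeR's quasi-likelihood test. Sorcs3 was at 0.0688, Kit at 0.131, Gad1 at 0.160 and Plcb3 at 0.0972 by edgeR. With 2 treated libraries left, the median went from −0.20 to −0.16 for interneuron markers, −0.13 to −0.07 for Purkinje markers and −0.14 to −0.12 for ion channels. For GABAergic genes it went from −0.15 to −0.10 and for glutamatergic genes from −0.09 to −0.05. The camera calls of the Purkinje, glutamatergic and GABAergic lists ended (0.0580, 0.0580 and 0.0552).

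Axon and cytoskeleton genes fell in 4 of 31 cases, 6 adjusted over the list alone, with the tubulin gene Tubb2b (150 to 106 CPM, −0.51, SE 0.0921) first (camera 0.0460, adjusted p = 0.755 with an estimated correlation). The camera call ended without FVB 2 (0.185) or 4 (0.0827), saline knockout 2 (0.0523), treated knockout 2 (0.0593), 3 (0.113) or 4 (0.0566). It also ended without the 3 libraries high in Ttr (0.176), with log2 Ttr as a covariate (0.135) and with 1 surrogate variable (0.239). Glucocorticoid-responsive genes rose in 4 of 23 cases, 6 adjusted over the list alone (camera 0.00110, adjusted p = 0.738 with an estimated correlation). Complement genes rose in 3 of 19 cases, 4 adjusted over the list alone (camera 0.0252, adjusted p = 0.722 with an estimated correlation). Heat shock genes rose in 3 of 28 with 1 fall, the same adjusted over the list alone (camera 0.0337, adjusted p = 0.722 with an estimated correlation). The complement call ended without FVB 3 (0.0545) or 4 (0.0897) or treated knockout 3 (0.144), and the heat shock call without FVB 1 (0.0992) or 3 (0.114) or treated knockout 2 (0.102). Without the 3 libraries high in Ttr edgeR called 1 glucocorticoid-responsive gene, 0 complement genes and 2 heat shock genes. The complement median went from 0.34 to 0.09 there. Of 24 choroid plexus markers edgeR's quasi-likelihood test called 0 (5 at an unadjusted p under 0.05, DESeq2 3, limma-voom 0), also 0 adjusted over the list alone, with a median of 2.28 (camera 0.0141, adjusted p = 0.755 with an estimated correlation). That call ended without treated knockout 2 (0.128) or 3 (0.0809), and without the 3 libraries high in Ttr the median was −0.12.

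**Figure D3:**
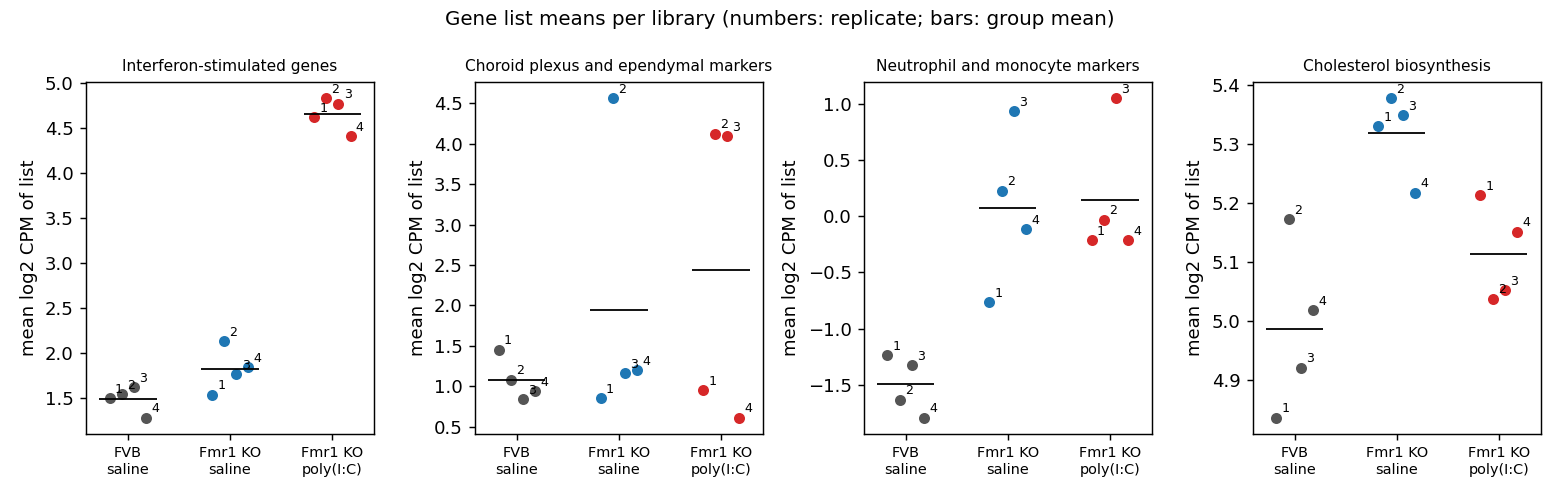
Mean log2 CPM of 4 gene lists (interferon-stimulated, choroid plexus and ependymal, neutrophil and monocyte, cholesterol biosynthesis) in each library, by group; each number is the replicate number of a library and horizontal bars are group means. Choroid plexus genes are high in saline knockout 2 and in treated knockout 2 and 3.

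Whether poly(I:C) moved genotype differences back toward FVB was asked by comparing signs. Of the 294 genes changed by genotype 209 (71.1%) had the opposite sign under poly(I:C), where 20 simulations with a genotype effect and no treatment effect gave 70.8% (68.3% to 74.0%), because both comparisons use the saline knockout libraries. Across all tested genes, which are not independent replicates, the correlation of the fold changes was −0.157, against −0.506 simulated with no effect and −0.256 simulated with a genotype effect alone. The covariance was −0.0357, against −0.0405 and −0.0428. The simulation with a genotype effect called 1007 genes for genotype on average where the data gave 294, so it is not an exact match. With the saline knockout libraries split 2 and 2 in all 6 ways the correlation averaged 0.0508 (−0.0304 to 0.120) and 54.3% of the genotype calls made within each split were opposite (42.8% to 58.6%). Among genes called in both comparisons 6 were up by genotype and down by poly(I:C) (1.65 for independent lists), 9 down and then up (2.50), 7 up in both (2.82) and 0 down in both (1.46). Independent lists are not the right reference where the comparisons share libraries. The simulation with a genotype effect alone gave 0.20 opposite genes, but also only 0.30 treatment calls, so it is no reference for this count. The 6 splits, each with fewer libraries, gave 3 to 7 opposite and 3 to 13 in the same direction, and no shared effect is called. In treated knockout against FVB 199 of the 294 genotype calls (67.7%) were also called in the same direction, and 0 in the opposite one. That comparison shares the FVB libraries with genotype, which also makes equal directions more common. By edgeR's quasi-likelihood test Vipr2 fell with genotype (−1.50) and rose with poly(I:C) (1.03), Nxpe4 did the reverse (1.73 and −0.76), and Gbp2b, Ifi44l, Mndal, Gbp6, Irgm2, Cth and Crym rose in both. Of these genes Ifi44l, Mndal, Gbp6, Irgm2, Cth and Crym were chosen after their values were seen.

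Because knockout and control lines can differ around the targeted gene and at coat colour or retinal genes, the genotype calls near 3 loci were counted, by position in the GRCm38 annotation. Within 20 Mb of Fmr1 2 of 145 tested genes were called, Fmr1 itself and Gabra3 (two-sided Fisher's exact test, adjusted p = 1.0), and within 20 Mb of the albino locus Tyr 3 of 306 (adjusted p = 0.954). Within 20 Mb of the retinal gene Pde6b 14 of 449 were called (Fisher's exact test, odds ratio 2.12, adjusted p = 0.0324). They included Crlf2 and Zfp605 and, chosen after their values were seen, Gbp6 and Pkd2. Within 10 Mb of Pde6b 13 of 244 were called (Fisher's exact test, odds ratio 3.73, adjusted p = 3.25e-04). The whole chromosome of Pde6b gave an odds ratio of 1.04 (Fisher's exact test, adjusted p = 0.813). Blocks of 10 Mb on other chromosomes held more calls, 14 of 91 tested genes on chromosome 12, with Vipr2 among them, and 11 of 116 on chromosome 9, with Nxpe4, Sc5d and Hspa8, against 10 of 107 in the densest block of chromosome 5, where Pde6b lies.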

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

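The tests of an explanation in this part were chosen after the result was seen. Within each group, the distance of the most extreme library from its nearest neighbour was divided by the range, and a library was marked where that ratio was too large for 4 values by Dixon's test. This marked 15 of 264 groups of values where about 1 in 20, or 13.2, are marked by chance, so most single marks need no cause.

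Saline knockout 4 had the most counts of its group, 50.2 M against 39.4 M for the next (ratio 0.9445). Saline knockout 3 had the lowest share in the 10 most abundant genes (5.24% against 6.06%, ratio 0.9308) and the lowest mitochondrial share (4.20% against 5.03%, ratio 0.8825). Among mean log2 CPM of lists, FVB 2 was high for cytokines, chemokines and NF-kB targets (1.585 against 0.7715, ratio 0.9269) and low for sex-linked genes (5.548 against 5.754, ratio 0.8583). Treated knockout 1 was low for granule cell markers (7.687 against 7.775, ratio 0.9072), treated knockout 2 for astrocyte markers (7.569 against 7.714, ratio 0.8683) and treated knockout 4 for lymphocyte markers (−1.073 against −0.7892, ratio 0.8538). Saline knockout 1 was high for oligodendrocyte precursor genes (4.829 against 4.717, ratio 0.9106), and treated knockout 3 for neutrophil and monocyte markers (1.053 against −0.03102, ratio 0.8552). Saline knockout 2 was high for choroid plexus markers (4.56 against 1.198, ratio 0.9066). Among genes on the log2 CPM scale, saline knockout 1 was high for Il17ra (3.888 against 3.546, ratio 0.9074) and Slc15a2 (4.807 against 4.195, ratio 0.86). FVB 2 was low for Lyrm7 (1.266 against 1.953, ratio 0.8758) and FVB 3 for Rsad2 (−0.8014 against −0.1191, ratio 0.8505).

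The choroid plexus mark belongs to a wider pattern, in which saline knockout 2 and treated knockout 2 and 3 were high. Of the 23 other tested choroid plexus genes 19 had the same 3 highest libraries as Ttr, where chance gives 0.455% per gene, and Enpp2 was at 1792, 1224 and 1221 CPM in them against at most 184.8 CPM elsewhere. This fits choroid plexus tissue carried along with some of the dissected samples. A response of every knockout library does not account for it, since 5 of the 8 knockout libraries, 3 saline and 2 treated, had no more Ttr than the highest FVB library. Of the 24 tested genes 15 had a mean of at least 1 CPM in FVB, and 1 was on another list, so the tissue itself may express some of them at a low level.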

How the results depend on the processing

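With 4 libraries per group and 35.2 to 56.4 M counts per library, genes near the floor of 3 counts over a group could not be compared. Of the named genes 25 of 38 calls for genotype, 43 of 68 for treatment and 70 of 114 for treated knockout against FVB were kept whichever library was left out, and of the called lists 7 of 12, 8 of 10 and 12 of 16. Without the libraries high in Ttr 31, 37 and 56 of the gene calls and 10, 9 and 9 of the list calls were kept. With fry all 12 list calls for genotype, 6 of 10 for treatment and 8 of 16 for treated knockout against FVB were lost, while the cytokine list for treatment kept its call (adjusted p = 0.00273), which the estimated correlation did not keep. Where a result changed, the cause was not tested unless the setting itself tests fewer libraries or sets another threshold.

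For genotype, DESeq2 called 627 genes, no low-count filter 506, an adjusted p under 0.1 494, a log2 fold change of at least 1 128, and leaving out single libraries 156 (FVB 3) to 300 (treated knockout 1). For treatment, DESeq2 called 971, an adjusted p under 0.1 917, a log2 fold change of at least 1 250, the fit without the libraries high in Ttr 215, and leaving out single libraries 347 (treated knockout 3) to 689 (saline knockout 4). For treated knockout against FVB, 1 surrogate variable called 805, an adjusted p under 0.1 2123, a log2 fold change of at least 1 439, the fit without the libraries high in Ttr 556, and leaving out single libraries 791 (treated knockout 3) to 1542 (saline knockout 4).

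The value of Il17rc, genotype, turned negative with 1 surrogate variable (−0.0445), with log2 Ttr as a covariate (−0.0176) and without the libraries high in Ttr (−0.0335), and ranged from −0.0566 to 0.143 over single libraries left out. That of Il17ra, genotype, ranged from −0.17 to 0.0089. Without the libraries high in Ttr the value of IL-17 signalling and targets, treatment, turned downward (adjusted p = 0.923, signed −0.923). That of Choroid plexus and ependymal markers, combined (treated knockout against FVB), turned downward with 1 surrogate variable (signed −0.426) and without those libraries (signed −0.0635). The correlation of the fold changes for opposite changes was 0.0508 with the saline knockout libraries split 2 and 2 and −0.226 over the genotype calls alone. Around Pde6b the odds ratio for the whole chromosome was 1.04.

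The labels give the groups the same replicate numbers without saying that they share anything. With a replicate block 274, 563 and 1322 genes were called in the 3 comparisons. Correlations of same-numbered libraries ran from −0.0987 to 0.145, and not every library correlated best with its own number. With the block Il17ra passed for treatment (edgeR, adjusted p = 0.0486), the IL-17 list passed for treated knockout against FVB (0.0165) and the axon list did not (0.0560). Of the named genes 1 call for genotype (Alpk1, 0.0606), 6 for treatment (among them Col2a1, 0.0769, and Cd9, 0.0528) and 6 for treated knockout against FVB (among them Cxcl1, 0.0592) were not made with the block.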

Other observations

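Several gene lists beyond those above held called genes without being called as a group, or held none, by camera and edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. For genotype, S100a8 and S100a9 were the called members of the 22 tested IL-17 genes (2 up and 1 down adjusted over the list alone, camera adjusted p = 0.263). The circadian clock list held 1 rise, Bhlhe41 (0.33), and was at 0.0837, and that call ended without FVB 3 (0.0649). Activated microglia genes for treatment held rises of Tspo, the translocator protein, and Ch25h (1.89), and a fall of Cd9 (−0.29), with the list at 0.563. Ch25h was not called without the 3 libraries high in Ttr (0.260). Astrocyte markers held a fall of Aqp4 (−0.36, list at 0.936), oligodendrocyte genes a rise of Apod (0.59) and the fall of Opalin (list at 0.150), and brainstem markers a fall of Th, the tyrosine hydroxylase gene (−1.04, list at 0.791). Extracellular matrix genes held falls of Lama4 (−0.70) and Tnc (list at 0.551), and autism risk genes a fall of Nlgn3 (−0.31, list at 0.655). By edgeR, leaving out single libraries ended the calls of Cd9 (any knockout library, adjusted p = 0.0558 to 0.112) and Aqp4 (saline knockout 2 to 4 and treated knockout 2 to 4, 0.0621 to 0.145). It also ended those of Nlgn3 (saline knockout 1 to 3 and treated knockout 2 and 3, 0.0620 to 0.118), Apod (saline knockout 3, 0.0621, and treated knockout 3, 0.0540) and Lama4 (saline knockout 1, 0.0702, and treated knockout 4, 0.0626). None of these 5 was called by edgeR without the 3 libraries high in Ttr (0.326, 0.724, 0.655, 0.242 and 0.101).

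For treated knockout against FVB, the IL-17 list held rises of Lcn2 and Cxcl1 (2.24) and was at camera adjusted p = 0.0930, which became 0.0422 without saline knockout 3 and 0.0262 without treated knockout 1. Oligodendrocyte precursor genes held a rise of Tns3 (0.59, list at 0.725), granule cell genes 2 rises and 1 fall (0.762), immediate early genes the fall of Nptx2 (0.762), and sex-linked genes a rise of Kdm5d (0.37, list at 0.762). By edgeR, the calls of Cxcl1, Nptx2 and Kdm5d ended without the 3 libraries high in Ttr (adjusted p = 0.370, 0.0838 and 0.103). That of Cxcl1 also ended without FVB 1, 3 or 4 or treated knockout 3 or 4 (0.0546 to 0.160), that of Nptx2 without FVB 2 or 4 or treated knockout 3 or 4 (0.0597 to 0.0771), and that of Tns3 without FVB 4 (0.0528) or treated knockout 3 (0.0511). Of 76 nuclear oxidative phosphorylation genes, 13 mitochondrially encoded genes and 11 erythrocyte genes none was called in any comparison by edgeR, DESeq2 or limma-voom. At an unadjusted p under 0.05 there were 1, 11 and 4 oxidative phosphorylation genes for genotype, treatment and treated knockout against FVB, 1, 0 and 0 mitochondrial genes and 1, 0 and 1 erythrocyte genes. Median, mean and test differed in sign for 5 lists for genotype (lymphocyte, erythrocyte, brainstem, mitochondrial, glucocorticoid), 2 for treatment (neutrophil, brainstem) and 6 for treated knockout against FVB (granule, oligodendrocyte, oligodendrocyte precursor, brainstem, autism risk, sex-linked), none of which was called.

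The tests of an explanation that follow were chosen after the results were seen. Each real grouping called more genes than every other split of its 8 libraries into 4 and 4. It was thus the 1 of 35 splits with as many calls, a rank that labels unrelated to expression give in 1 of 35 cases. The other splits mix the 2 groups, so their counts are not a level of false calls. The rank does not tell genotype or treatment from any other difference between the groups. For genotype the real split called 294 genes and the highest other 29, for treatment 550 and 8, and for treated knockout against FVB 1352 and 0.

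Genes called for genotype lay near one another on the chromosomes. With 1 gene kept per family, 497 pairs lay within 5 Mb against 205 in 10000 random draws, a ratio of 2.422 (permutation p = 1e-04, the smallest the draws can give), while treatment calls gave 1.19 (permutation p = 0.0025), also more than their draws, and 1.055 without predicted genes (p = 0.209). The ratio was 2.113 without predicted genes, so reads shared between neighbouring copies do not account for it, 2.37 without chromosome X, so the segment around Fmr1 alone does not, and 1.79 without the 3 densest blocks of 10 Mb. Treated knockout against FVB sets the same lines against each other, but its ratio was lower (1.056, permutation p = 0.0443, 1.13 with all genes, p = 2.0e-04, and 0.986 without predicted genes, p = 0.649). It counts 1239 calls in place of 281. Whether the added calls lower the ratio was not tested, so this comparison decides nothing. The genotype ratio would fit chromosome segments that differ between the lines, so some calls may not come from the loss of Fmr1, but local co-regulation was not tested and no sequence variants were analysed here.

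Neutrophil and monocyte genes had a median log2 fold change of 2.10 in the saline knockout, where edgeR called 4 of 17 and limma-voom 0. The list call was lost with an estimated correlation (camera, adjusted p = 0.508) and with fry (adjusted p = 0.132). Blood left in the samples was tested first by asking whether hemoglobin genes could have risen as much as the list median of 2.10, with log2 fold changes plus 2 SE reaching 4.05 for Hba-a2 but 0.785, 1.34 and 1.36 for Hba-a1, Hbb-bs and Hbb-bt. That test was replaced, after its values were seen, by the list mean minus the summed hemoglobin level, which was 1.316 higher in the saline knockout on the log2 scale (exact permutation p = 0.286), so more blood can neither be excluded nor shown. The median was 2.17 without the libraries high in Ttr, so choroid plexus tissue does not account for it. Of the 17 tested genes 2 had a mean of at least 1 CPM in FVB and 4 were on another list.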
